A study of Oryza sativa with 3 samples.

How the data were processed

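Per the labels, RNA came from the youngest fully expanded leaves of hydroponic weedy red rice given NH4NO3, was amplified (MessageAmp II) and labelled with Cy5 for the control and Cy3 for the treated extract of each comparison, with no dye swap. Per the file headers, each array was scanned with a GenePix instrument at 635 nm (Cy5) and 532 nm (Cy3) and quantified with GenePix Pro 6.1.0.4. The intensity values are foreground and local background pixel brightness with no normalization by the software, per the file headers. The percent values give the share of saturated pixels in a spot, as deposited by the scanner software. The score values of the separate table are log ratios of control over treated that the authors combined per comparison, with log base, centring and combination not stated. Replicate numbers come from folder names in the file headers and were not taken to pair the extracts. For the 24 h files of slide A, 2 header fields give different replicate numbers. The image folder was used, and the numbers exchanged were run as an alternative added after seeing the data. The labels state 4 biological replicates, while the deposited files hold 2 hybridisations per comparison, each on 1 slide A and 1 slide B, or 12 arrays.

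Log2 ratios of Cy3 over Cy5 were computed in R 4.3.3 with limma 3.58.1 from mean foreground and median local background, using normexp with an offset of 50, global loess within arrays and no scaling between arrays. Spots the scanner software marked as bad, absent or not found had weight 0, and spots of a probe were averaged. Of 21660 plant probes on slide A and 21651 on slide B, those more than 2 background standard deviations above background in at least 1 channel on at least 0.5 of the arrays were tested, 3429 and 3309 in number. Each slide was fitted with a coefficient per comparison (3 residual degrees of freedom, prior degrees of freedom 4.28 and 5.17), so the comparisons share an estimate of the spread. P-values were two-sided and adjusted by Benjamini-Hochberg over both slides, with a threshold of 0.05. Contrasts were 48 h minus 24 h, the mean of the 3 coefficients (dye), and 0.5 of the difference between the starvation coefficient and the mean readdition coefficient, in which a constant dye bias cancels. A ratio with 1 side at background or at least 50% saturated pixels on all of its arrays is given as a bound, and so is a contrast that uses it. On data simulated with 2 arrays per comparison, 71.6% of 2-fold changes were recovered for starvation and for 24 h and 88.1% for 48 h. Of the calls 4.72%, 7.63% and 5.71% were false. The simulated noise was independent between arrays and of equal spread in all comparisons, with no shared starved extract and no dye bias. These rates may therefore not hold for the real arrays.

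The 31 gene lists, the tests, the settings and the rule for naming genes were fixed before the data were examined, except where stated. Lists were drawn from words in the gene descriptions and hold at least 5 tested probes each. They cover N uptake and assimilation, light harvesting, photosystems, Calvin cycle, photorespiration, chlorophyll synthesis and breakdown, ribosomes, protein breakdown, amino acid synthesis and transport, phenylpropanoids, starch and sucrose, glycolysis, pentose phosphate, phosphate starvation, stress, transcription factors, hormones, aquaporins, and markers of dividing, expanding, vascular, epidermal and root cells. Each was tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison, and with fry. The rule named, for each probe test, the 12 largest rises and 12 largest falls among probes with a description, an adjusted p under the threshold, the same sign on each array and signal above background on each array of a channel. Where fewer than 5 passed, the 5 smallest unadjusted p were named as not passed. Members of the N list and up to 4 of each other list with the smallest p were also named.

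Correlations between comparisons were taken across probes and set against simulated unchanged groups sharing a starved extract. Alternatives were print-tip loess, median centring, Aquantile scaling, no background correction, median foreground, no filter, marked spots kept, array weights, trended robust moderation, only the arrays compared, probes of a gene averaged, a log2 threshold of 1, the authors' table and each replicate left out. A replicate block, saturated readings left out, and further settings for the gene lists were added after seeing the data. No array was left out. Figures were drawn with matplotlib 3.10.9.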

Results

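Leaf transcripts of a strawhull weedy red rice accession were compared on spotted oligonucleotide arrays between plants on full N, plants starved of N, and starved plants given N back for 24 h or 48 h. The youngest fully expanded leaves were sampled, and each comparison set a treated extract labelled Cy3 against its control labelled Cy5. Comparison 1 set starved against full N leaves, and the others set leaves after 24 h and after 48 h of N readdition against starved leaves. Each comparison had 2 hybridisations, and a hybridisation was a set of 2 slides with different probes, so n = 2 for each ratio below except where 1 array is stated. Of the plant probes on an array, 10.2% to 20.3% lay more than 2 background standard deviations above the local background in Cy5 and 9.02% to 17.2% in Cy3. The number of arrays limits the precision of every value. The analysis covered 6738 probes. Log2 ratios are treated over control, positive where the treated leaves were higher. The ± gives limma's standard error, from a spread pooled over the 3 comparisons.

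The first comparison addressed which leaf transcripts differ between starved and N-sufficient plants. Nitrite reductase (LOC_Os01g25484), the plastid enzyme that turns nitrite into ammonium, was 11.1-fold lower in starved leaves, a log2 ratio of -3.48 ± 0.18 (adjusted p = 0.000249, lower on 2 of 2 arrays). Chloride channel protein CLC-a (LOC_Os12g25200), of a family that includes vacuolar nitrate transporters, fell by 2.49 ± 0.19 on the log2 scale. Among the probes that rose were beta-fructofuranosidase 1 (LOC_Os02g01590), which splits sucrose, with a log2 ratio of 2.0 ± 0.19, and a sugar transporter family protein (LOC_Os12g32760) at a log2 ratio of 1.96 ± 0.22. A tryptophan/tyrosine permease family protein (LOC_Os03g14910) rose by 1.76 ± 0.19, a papain family cysteine protease (LOC_Os03g54130) by 1.66 ± 0.17 and a senescence-associated protein (LOC_Os06g13680) by 1.59 ± 0.18.

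In all, 149 probes were higher and 195 lower in starved leaves at an adjusted p under 0.05. Other probes that fell were inositol 1,3,4-trisphosphate 5/6-kinase (LOC_Os03g51610) at -2.65 ± 0.26, nudix hydrolase 8 (LOC_Os04g46280) at -2.43 ± 0.20 and a DnaJ domain protein (LOC_Os08g35160) at -2.42 ± 0.51, with -3.68 and -1.15 on its arrays. The treated reading of nudix hydrolase 8 lay at background on 1 of 2 arrays. Falls also passed for a wound-responsive protein (LOC_Os08g26870) at -2.35 ± 0.28, the iron store ferritin 1 (LOC_Os12g01530) at -2.21 ± 0.23 (control saturated on 1 of 2 arrays) and ferredoxin-2 (LOC_Os01g64120) at -2.19 ± 0.20. The vacuolar water channel aquaporin TIP1.1 (LOC_Os01g74450) fell by 2.09, and trehalose-6-phosphate synthase (LOC_Os02g54820) fell by 1.68. Other probes that rose were an Hsp20 chaperone (LOC_Os02g54140) at 1.86 ± 0.20 and a SacIy domain protein (LOC_Os02g54150) at 1.83 ± 0.20. Further rises were a glutathione S-transferase (LOC_Os09g29200) at 1.49 ± 0.18, flavonoid 3'-monooxygenase (LOC_Os10g17260) at 1.48 ± 0.20 and the early light-induced protein (LOC_Os01g14410) at 1.42 ± 0.18. The direction of the balance depended on the normalization: with median centring alone, 181 probes were higher and 90 lower, and the median of all probes was 0.21 (0.14 at 24 h and -0.14 at 48 h). The count of 344 became 0 with only the arrays compared, 40 with no filter on dim probes, 145 with a replicate block, a setting chosen after seeing the data, and 590 with array weights. Without starved replicate 1 or 2 it was 14 and 7 probes, without either 24 h replicate 620 and without either 48 h replicate 77. Of 52 named probes past the test 3 (nitrite reductase, CLC-a and chlorophyll a-b binding protein 1) passed in every such fit.

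Among 20 light harvesting probes, which bind chlorophyll around the photosystems, 9 fell and none rose in starved leaves over all probes tested, or 13 and 0 adjusted over the list alone. The list median was -0.98 (camera adjusted p = 2.43e-15, and adjusted p = 0.688 with an estimated correlation). Chlorophyll a-b binding protein 1 (LOC_Os09g17740) stood at -2.43 ± 0.18 and protein 4 (LOC_Os08g33820) at -1.55 ± 0.18. Protein 2 (LOC_Os01g41710) was at least 5.22-fold lower, a bound because its control readings were saturated on 2 of 2 arrays, and 13 of the 20 probes were saturated on at least 1 array. Of 33 photosystem probes, 5 fell (13 adjusted over the list alone; list median -0.34, camera adjusted p = 6.93e-07, and adjusted p = 0.688 with an estimated correlation). They included photosystem I subunit III (LOC_Os03g56670) at -1.65 and subunit VI (LOC_Os05g48630) at -1.27. Of 26 Calvin cycle probes, 3 fell (1 higher and 6 lower adjusted over the list alone; list median -0.30, camera adjusted p = 0.00888, and adjusted p = 0.688 with an estimated correlation). They were Rubisco small chains, the carboxylating enzyme's small subunit, at -1.66 ± 0.25 (LOC_Os12g17600), -1.27 ± 0.18 (LOC_Os12g19394) and -1.39 ± 0.30 (LOC_Os12g19470). Of 17 chlorophyll synthesis probes, 2 fell (5 adjusted over the list alone; camera adjusted p = 0.0399, and adjusted p = 0.688 with an estimated correlation): protochlorophyllide reductase B (LOC_Os10g35370) at -1.26 ± 0.24 and geranylgeranyl hydrogenase (LOC_Os02g51080) at -0.98 ± 0.21. Control readings were saturated on 1 of 2 arrays for chlorophyll a-b binding proteins 1 and 4 and photosystem I subunit III. The same held for the Rubisco chain LOC_Os12g17600 and geranylgeranyl hydrogenase. A saturated control by itself understates a fall, but a dye bias could add to it. With the dye cancelled, LOC_Os12g17600 stood at -0.33 and did not pass (limma adjusted p = 0.158). Chlorophyll a-b binding proteins 1 and 4 stood at -1.37 and -0.84 in that contrast and passed. The Rubisco chain LOC_Os12g19394 also passed as lower at 48 h than in starved leaves, the same direction as in starvation, so dye bias may be part of its fall. For it the authors' table, with the sign turned, has -0.0016 in starvation and 0.17 at 48 h. The Calvin cycle call was lost without starved replicate 1 (median -0.13) or without background correction (camera adjusted p = 0.0916). The list was not called with the dye cancelled. Its medians on the readdition arrays went both ways, -0.31 and 0.14 at 24 h and 0.08 and -0.48 at 48 h. The chlorophyll synthesis call was lost without starved replicate 1 (0.0643), starved replicate 2 (0.209) or either 24 h replicate (0.0537). It was also lost without background correction (0.0981), with print-tip loess (0.117) and with saturated readings left out (0.0683).

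The N uptake and assimilation list held opposite movers in starved leaves. Of its 17 probes, nitrite reductase fell, and ammonium transporter 1 member 2 (LOC_Os04g43070), which carries ammonium into cells, rose by 0.96 ± 0.19. The member number is the array's description of LOC_Os04g43070 and was not checked against another source. Adjusted over the list alone, 1 probe was higher and 2 lower, with a list median of -0.28 (camera adjusted p = 0.025, and adjusted p = 0.809 with an estimated correlation). The 2 probes for the nitrate reductase pair LOC_Os08g36480/LOC_Os08g36500, whose enzyme reduces nitrate to nitrite, differed in sign, with log2 ratios of -1.07 (adjusted p = 0.054) and 0.15, and neither passed. The plastid glutamine synthetase (LOC_Os04g56400) at -0.46, the other glutamine synthetase (LOC_Os02g50240) at -0.56 and -0.35 on its 2 probes, asparagine synthetase (LOC_Os06g15420) at 0.01 and a nitrate transporter (LOC_Os06g38294) at -0.43 did not pass either. The list's call was lost without starved replicate 1 (median 0.11, adjusted p = 0.142) or 2 (adjusted p = 0.0709), without background correction (0.0981) and with print-tip loess (0.117). The pentose phosphate and reductant list was called lower (21 probes, camera adjusted p = 0.00297, and adjusted p = 0.688 with an estimated correlation). Its 2 probes that fell were ferredoxin-2, an electron carrier, and nitrite reductase, which is also on the N list, while 1 was higher and 4 lower adjusted over the list alone. That list's median was -0.09, its mean -0.36, and its median turned to 0.12 with median centring alone. It was -0.05 without starved replicate 1, with the call kept.

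The second comparison addressed which transcripts moved within 24 h of N readdition. Relative to starved leaves, nitrite reductase rose 9.94-fold (log2 ratio 3.31 ± 0.18, adjusted p = 0.000366, higher on 2 of 2 arrays). Of 115 cytosolic ribosome probes 61 rose, and of 26 phenylpropanoid and flavonoid probes 7 fell, and neither list call held with an estimated correlation (adjusted p = 0.217 and adjusted p = 0.368 with an estimated correlation). The tryptophan/tyrosine permease probe (LOC_Os03g14910) fell by 2.38 ± 0.19 and the papain family protease (LOC_Os03g54130) by 2.09 ± 0.17 (control saturated on 1 of 2 arrays).

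At 24 h, 536 probes were higher and 411 lower. The probes that rose furthest after nitrite reductase included the DnaJ domain protein (LOC_Os08g35160) at 2.98 ± 0.51, a rhodanese-like protein (LOC_Os09g36040) at 2.93 ± 0.17, the inositol kinase (LOC_Os03g51610) at 2.87 ± 0.26 and a CCT motif protein (LOC_Os02g49880) at 2.81 ± 0.20. A Bowman-Birk serine protease inhibitor (LOC_Os03g60840) rose by 2.60 ± 0.23, nudix hydrolase 8 (LOC_Os04g46280) by 2.55 ± 0.20, CTP synthase (LOC_Os01g43020), which makes CTP from UTP, by 2.29 ± 0.32 and TIP1.1 (LOC_Os01g74450) by 2.24 ± 0.21. Trehalose-6-phosphate synthase (LOC_Os02g54820) rose by 2.22 ± 0.21. Among those that fell were flavonoid 3'-monooxygenase (LOC_Os10g17260) at -2.22 on 1 array, a peroxidase (LOC_Os10g39170) at -1.95 ± 0.20, an MtN3/saliva family protein (LOC_Os01g50460) at -1.82 ± 0.22 and beta-expansin 1a (LOC_Os10g40720) at -1.76 ± 0.23 (control saturated on 1 of 2 arrays), and pyruvate decarboxylase 1 (LOC_Os05g39320) was at least 3.54-fold lower. For beta-expansin 1a the authors' table, with the sign turned, has the other direction, 0.0501 at 24 h and 0.42 at 48 h. On the N list ammonium transporter 1 member 2 (LOC_Os04g43070) fell by 1.27 and a nitrate-induced NOI protein (LOC_Os04g52950) by 0.69. The list was not called (17 probes, 1 higher and 2 lower both over all probes and adjusted over the list alone, camera adjusted p = 0.875). With median centring alone, 482 probes were higher and 154 lower at 24 h. The count of 947 became 46 with only the arrays compared, 262 with array weights, 360 with no filter and 589 with a replicate block. At 24 h, a channel lay at background on 1 of 2 arrays for nudix hydrolase 8, CTP synthase, the peroxidase and the NOI protein. The count was 417 without 24 h replicate 1, 1018 without replicate 2 and 429 without either 48 h replicate.

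Of 115 cytosolic ribosome probes, 61 rose and none fell at 24 h (93 and 1 adjusted over the list alone), with a list median of 0.76 (camera adjusted p = 1.61e-29, and adjusted p = 0.217 with an estimated correlation). Examples were ribosomal proteins S26 (LOC_Os05g39960) at 1.76, S4 (LOC_Os02g01560) at 1.74 and L21 (LOC_Os10g32820) at 1.51. The same list's median was 0.08 in starved leaves, and 0.34 in the mean of the 3 comparisons, in which 38 of its probes passed. Of 33 plastid ribosome probes, 7 rose (12 adjusted over the list alone; list median 0.55, camera adjusted p = 0.000283, and adjusted p = 0.381 with an estimated correlation). Examples were plastid-specific ribosomal proteins 1 (LOC_Os03g63950) at 1.29 and 2 (LOC_Os09g10760) at 0.89. The list median was 0.34 without 24 h replicate 2, with the call kept. Of 28 amino acid synthesis probes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0069, and adjusted p = 0.368 with an estimated correlation). Aspartate kinase (LOC_Os03g63330), the entry to lysine and threonine synthesis, rose by 1.65, threonine synthase (LOC_Os01g49890) by 1.16, an isochorismate synthase family protein (LOC_Os09g19734) by 1.20 and alanine aminotransferase 2 (LOC_Os07g01760) by 0.79. Chorismate mutase (LOC_Os01g55870) fell by 0.74. The list was drawn from words in the descriptions, so a member such as the isochorismate synthase family protein need not make an amino acid. Of 17 chlorophyll synthesis probes, 3 rose (6 adjusted over the list alone; list median 0.54, camera adjusted p = 0.0196, and adjusted p = 0.381 with an estimated correlation). They were protochlorophyllide reductase B (LOC_Os10g35370) at 1.54, coproporphyrinogen III oxidase (LOC_Os04g52130) at 1.27 (1.91 and 0.63 on its arrays) and uroporphyrinogen decarboxylase (LOC_Os03g21900) at 1.07. The call was lost without 24 h replicate 2 (adjusted p = 0.126) and with print-tip loess (0.0575). A channel lay at background on 1 of 2 arrays for S26 and the isochorismate synthase family protein.

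The pentose phosphate and reductant list was called higher at 24 h (camera adjusted p = 0.0196, and adjusted p = 0.576 with an estimated correlation), with 3 probes higher and 1 lower both over all probes and adjusted over the list alone. Those higher were nitrite reductase, plastid glucose-6-phosphate dehydrogenase 2 (LOC_Os07g22350) at 1.23, which feeds the pentose phosphate pathway, and ferredoxin-2 (LOC_Os01g64120), at least 2.14-fold higher, and leaf ferredoxin-NADP reductase (LOC_Os06g01850) fell by 1.02. Of 26 phenylpropanoid and flavonoid probes, 7 fell and none rose (10 adjusted over the list alone; list median -0.59, camera adjusted p = 0.000283, and adjusted p = 0.368 with an estimated correlation). Trans-cinnamate 4-monooxygenase (LOC_Os05g25640), an early step of the pathway, fell by 1.63 and chalcone synthase (LOC_Os11g32650), the entry to flavonoids, by 1.48 (-2.07 and -0.89 on its arrays). Markers of expanding cells moved with readdition: 5 of 14 probes fell (8 adjusted over the list alone; list median -0.71, camera adjusted p = 0.000236, and adjusted p = 0.777 with an estimated correlation). These included the wall-loosening beta-expansins LOC_Os10g40720 and LOC_Os03g01270, the latter at -1.21, and xyloglucan endotransglucosylase/hydrolase 15 (LOC_Os04g51460) at -1.35. Of 17 probes for abscisic acid, ethylene and auxin, 4 fell (5 adjusted over the list alone; camera adjusted p = 0.0178, and adjusted p = 0.984 with an estimated correlation). They included the auxin-responsive protein IAA9 (LOC_Os05g14180) at -1.42, the ethylene-forming 1-aminocyclopropane-1-carboxylate oxidase (LOC_Os05g05670) at -1.40 and a dehydrin (LOC_Os11g26760) at -1.27. A channel lay at background on 1 of 2 arrays for glucose-6-phosphate dehydrogenase 2, LOC_Os03g01270, LOC_Os04g51460 and the dehydrin. Without 24 h replicate 1 the calls of the hormone list (median -0.21, from -0.41, adjusted p = 0.524), the expanding cell list (-0.44, 0.0505) and the pentose phosphate list (0.0855) were lost. The last was also lost without 24 h replicate 2 (median 0.14, from 0.25, adjusted p = 0.0857). The expanding cell median was -1.12 without that replicate, with the call kept, and the call was lost with no filter (adjusted p = 0.199).

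The 24 h files of slide A carry different replicate numbers in 2 header fields, so which slides form 24 h replicate 1 or 2 is uncertain. With the slide A numbers exchanged, the 24 h count was 768 without replicate 1 and 606 without replicate 2. Calls at 24 h then lost without replicate 1 were chlorophyll synthesis (adjusted p = 0.0937), plastid ribosome (0.0678), pentose phosphate (0.0678) and hormone (0.133). Lost without replicate 2 were amino acid synthesis and pentose phosphate (0.188 each). The cytosolic ribosome, phenylpropanoid and expanding cell calls at 24 h were kept in both.

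**Figure D1:**
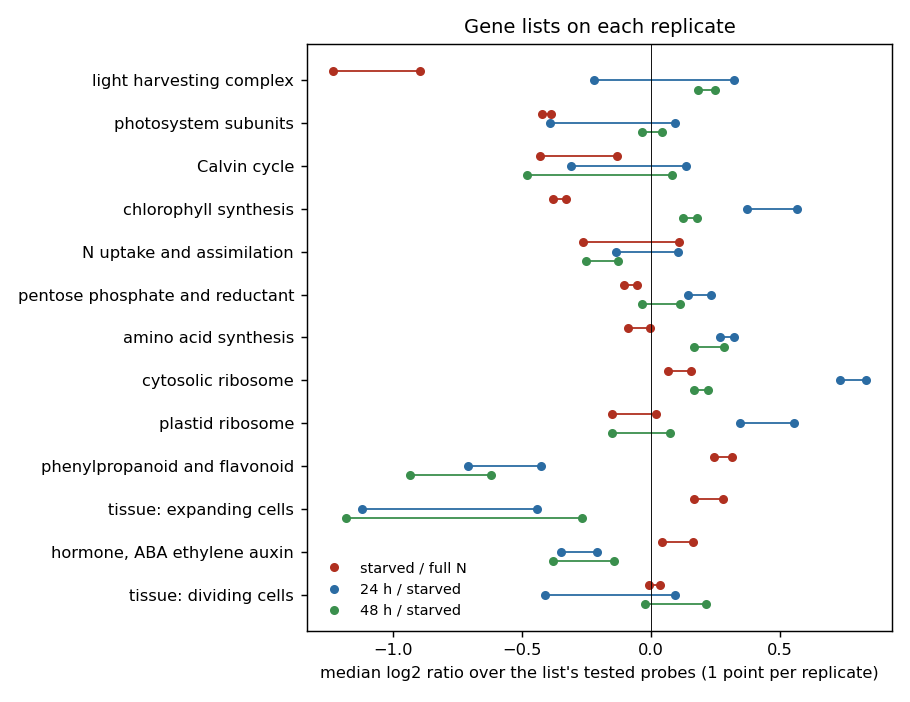
Median log2 ratio over each list's tested probes (x axis), with 1 point per replicate and a line joining the 2 replicates of a comparison. At 24 h the cytosolic ribosome list's median was 0.76 over both replicates, against 0.21 at 48 h; no list call held with an estimated correlation.

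The third comparison asked the same at 48 h of readdition. Nitrite reductase stood 9.47-fold above its starved level (3.24 ± 0.18, adjusted p = 0.000434, higher on 2 of 2 arrays), and the inositol kinase (LOC_Os03g51610) rose by 3.07 ± 0.26, TIP1.1 (LOC_Os01g74450) by 2.53 ± 0.21, ferredoxin-2 (LOC_Os01g64120) by 2.49 ± 0.20 and CLC-a (LOC_Os12g25200) by 2.46 ± 0.19. The control reading of the last 2 lay at background on 1 of 2 arrays. Beta-fructofuranosidase 1 (LOC_Os02g01590) fell by 2.52 ± 0.19 (control saturated on 1 of 2 arrays). For it the authors' table, with the sign turned, has -0.0045 at 48 h and -1.08 at 24 h. The tryptophan/tyrosine permease (LOC_Os03g14910) fell by 2.25 ± 0.19 and the papain family protease (LOC_Os03g54130) by 2.12 ± 0.17. Of 26 phenylpropanoid and flavonoid probes 10 fell, and the list call did not hold with an estimated correlation (adjusted p = 0.56 with an estimated correlation).

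At 48 h, 275 probes were higher and 412 lower. Others that rose were the rhodanese-like protein (LOC_Os09g36040) at 2.41 ± 0.17, aspartate kinase (LOC_Os03g63330) at 2.37 ± 0.21 and a metallothionein-like protein (LOC_Os05g11320) at 2.27 ± 0.49. Nudix hydrolase 8 (LOC_Os04g46280) rose by 2.26 ± 0.20. CTP synthase (LOC_Os01g43020) rose by 2.15 ± 0.32. Others that fell were a RADIALIS-like protein (LOC_Os01g47370) at -2.76 ± 0.58 and flavonoid 3'-monooxygenase (LOC_Os10g17260) at -2.19 ± 0.20. Some readings lay at background in the readdition channel and gave bounds: a protein phosphatase 2C (LOC_Os09g15670) was at least 5.06-fold lower, branched-chain amino acid aminotransferase 5 (LOC_Os03g12890) at least 4.06-fold and the Hsp20 chaperone (LOC_Os02g54140) at least 3.13-fold. With median centring alone, 120 probes were higher and 431 lower, and without background correction 377 were higher and 371 lower. The count of 687 became 1744 with only the arrays compared, 1671 with array weights, 454 with no filter and 388 with a replicate block. It was 0 without 48 h replicate 1 or without replicate 2, and 1137 without either 24 h replicate.

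Of 26 phenylpropanoid and flavonoid probes, 10 fell and none rose at 48 h (14 lower and 1 higher adjusted over the list alone; list median -0.73, camera adjusted p = 2.12e-05, and adjusted p = 0.56 with an estimated correlation). Flavonol 3-O-glucosyltransferase 5 (LOC_Os06g18670) fell by 2.15 ± 0.29, trans-cinnamate 4-monooxygenase (LOC_Os05g25640) by 1.88, chalcone-flavanone isomerase (LOC_Os12g02370) by 1.83 and chalcone synthase (LOC_Os11g32650) by 1.60. The list call was lost with no filter (adjusted p = 0.189). The enzyme 4-coumarate-CoA ligase 2 (LOC_Os02g46970) was at least 2.68-fold lower. Markers of expanding cells fell alongside, with 4 of 14 probes lower (6 adjusted over the list alone; list median -0.67, camera adjusted p = 0.00772, and adjusted p = 0.974 with an estimated correlation). That call was lost without 48 h replicate 2 (median -0.27, adjusted p = 0.476) and with no filter (0.801), and the median was -1.18 without replicate 1, with the call kept. Of 28 amino acid synthesis probes, 4 rose (6 adjusted over the list alone; camera adjusted p = 0.00527, and adjusted p = 0.56 with an estimated correlation). These included aspartate kinase and threonine synthase (LOC_Os01g49890), at 1.14. The list median was 0.16, and 0.28 without 48 h replicate 1 with the call kept, and the call was lost with no filter (adjusted p = 0.0528). Of 115 cytosolic ribosome probes, 10 rose both over all probes and adjusted over the list alone (list median 0.21, camera adjusted p = 0.000145, and adjusted p = 0.639 with an estimated correlation), S14 (LOC_Os02g33140) by 0.93 among them. The pentose phosphate and reductant list was called higher (camera adjusted p = 0.0202, and adjusted p = 0.974 with an estimated correlation) although its members went both ways, 4 higher and 3 lower on both counts, and its median of 0.07 turned to -0.0039 with median centring alone. The median was -0.03 and 0.11 without 48 h replicates 1 and 2, and the call was lost with no filter (adjusted p = 0.0804). Ferredoxin-2 and glucose-6-phosphate dehydrogenase 2 (LOC_Os07g22350, at least 3.64-fold) were higher, while ferredoxin-1 (LOC_Os08g01380) was at least 2.19-fold lower and ferredoxin-3 (LOC_Os03g61960) fell by 0.73. On the N list 1 probe was higher and 2 lower (1 and 3 adjusted over the list alone) and the list was not called (camera adjusted p = 0.962). The NOI proteins LOC_Os04g52950 (at least 1.87-fold) and LOC_Os03g63140 (-0.79, with a channel at background on 1 of 2 arrays) fell, and ammonium transporter 1 member 2 (LOC_Os04g43070) stood at -0.57 (adjusted p = 0.104).

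The difference between 48 h and 24 h was tested directly, as a contrast of the readdition comparisons. The lists of cytosolic and plastid ribosomes lay lower at 48 h than at 24 h, with median differences of -0.58 (115 probes, camera adjusted p = 1.27e-19) and -0.55 (33 probes, camera adjusted p = 5.43e-05). With an estimated correlation these calls were lost (adjusted p = 0.353 and adjusted p = 0.973 with an estimated correlation). With median centring alone the median differences were -0.83 and -0.89, with both calls kept. Markers of dividing cells lay higher at 48 h (24 probes, median difference 0.26, camera adjusted p = 0.00435, and adjusted p = 0.973 with an estimated correlation). That call was lost with median centring alone (median -0.06, adjusted p = 0.0851), without background correction (0.103) and with no filter (median 0.02, adjusted p = 0.388). It was also lost without 24 h replicate 1 (median 0.05, adjusted p = 0.747) or 48 h replicate 2 (median 0.15, adjusted p = 0.0649). With the 24 h slide A numbers exchanged, the plastid ribosome call was lost without 24 h replicate 1 (adjusted p = 0.0564) and the dividing cell call without 24 h replicate 2 (0.138). No single probe on these lists passed, over all probes or adjusted over the list alone. Limma called 0 of 6738 probes for this contrast, with 780 at an unadjusted p under 0.05, and it called 1 without 24 h replicate 1. Among those with the smallest p, none of which passed (adjusted p = 0.347 for each), the CCT motif protein LOC_Os02g49880 differed by -1.89 ± 0.28, ribosomal protein S26 (LOC_Os05g39960) by -1.31 ± 0.24 and an ATP synthase delta subunit (LOC_Os03g52660) by 1.23 ± 0.22. On data simulated without a shared extract or dye bias, this contrast recovered 22.4% of 2-fold and 95.5% of 4-fold changes. Of its calls there, 13.2% were false. The 24 h and 48 h arrays were scanned on different days. Median background was 77 to 277 at 24 h and 479 to 897 at 48 h, and 10.9% to 20.3% against 9.02% to 11.8% of plant probes lay more than 2 background standard deviations above it. So scan day and time of readdition cannot be told apart.

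Among probes that passed in starvation, most had a ratio of the other sign on readdition, 92.7% at 24 h and 91.6% at 48 h. Over all tested probes the share was 64.9% and 61.4%, no higher than the 66.4% in simulated unchanged groups that share a starved extract. With a shared extract, picking probes by their starvation ratio itself raises the share of opposite signs. No simulated share was computed for probes picked in that way. Of the 149 that rose in starved leaves, 141 had a negative ratio at 24 h, of which 96 passed, and of the 195 that fell, 178 had a positive one, of which 120 passed. At 48 h, 141 and 174 lay opposite, of which 68 and 95 passed. The median log2 ratio of starved over full N leaves was 1.04 for the risen and -1.20 for the fallen probes. Over starved leaves, the risen probes had medians of -0.91 at 24 h and -0.57 at 48 h. Those of the fallen probes were 0.98 and 0.81. Across all tested probes, which are not independent replicates, Pearson's r between starvation and readdition was -0.55 at 24 h and -0.48 at 48 h (Spearman's rho -0.46 and -0.37). Starved leaves stood in both comparisons, and simulated unchanged groups sharing a starved extract gave r of -0.49 and -0.50, so r itself says little. The covariance was -0.145 and -0.118 against -0.025 and -0.0251 in the simulation. Independent lists of these sizes would share 9.09 risen and 15.5 fallen probes with opposite calls at 24 h, and 9.11 and 7.96 at 48 h. Neither value allows for both real effects and shared extracts, and part of the excess may come from the shared starved extracts, which are too few to split.

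**Figure D2:**
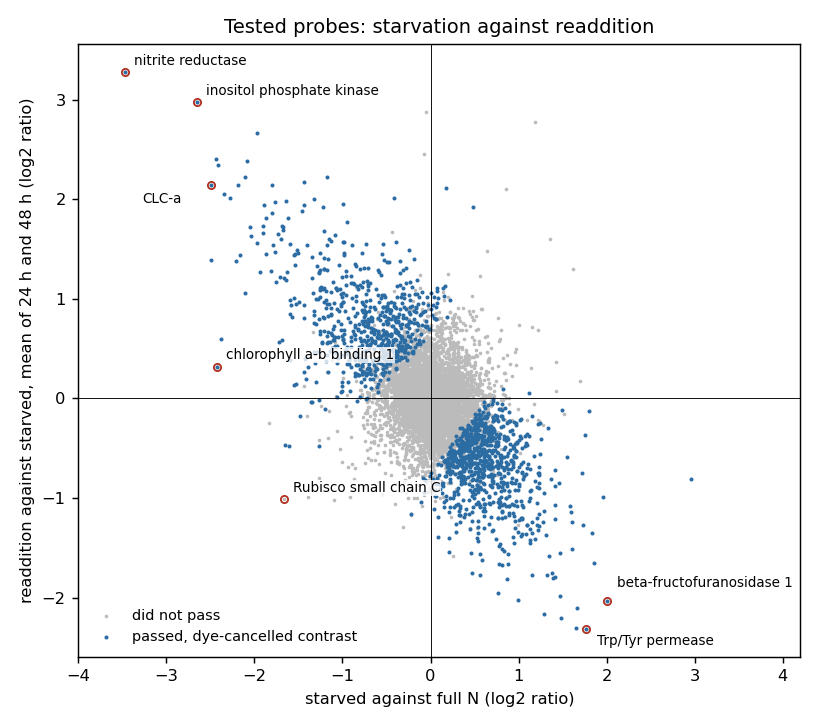
Each point is 1 of 6738 tested probes, with the log2 ratio of starved over full N leaves (x axis) against the mean log2 ratio of readdition over starved leaves at 24 h and 48 h (y axis). Nitrite reductase lies at -3.48 on the x axis; blue points passed the contrast in which the dye cancels (1519 probes), and circles mark the labelled genes.

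The changes at 24 h and 48 h resembled each other. Across probes r was 0.69 (rho 0.62), with a covariance of 0.202 against 0.0251 in simulated unchanged groups sharing the starved extract, whose r was 0.50. Of the probes called at both times 357 were called the same way and 0 opposite ways, 178 higher and 179 lower, and simulated unchanged groups sharing the starved extract had a mean of 0.1 called in both. That simulation holds no real effects, so it does not show how many calls a shared extract adds to them. Over the 3 comparisons, 139 probes were called in each, and 136 of them moved opposite ways in starvation and in readdition. The other 3, named after their values were seen, moved 1 way throughout. The homeodomain protein JUBEL2 (LOC_Os01g62920) was higher at 1.35, 2.17 and 1.04. Rubisco small chain C (LOC_Os12g17600) was lower at -1.66, -0.95 and -1.07 (control saturated on 1 of 2 arrays in starvation and at 48 h), and carbonic anhydrase (LOC_Os01g45274) lower at -0.86, -0.67 and -0.73. Cy3 always carried the treated extract, so dye and treatment cannot be told apart for probes of this kind. In the mean of the 3 comparisons camera called 2 of 31 lists higher and 7 lower, none of them with an estimated correlation. In that mean 217 probes lay above and 189 below 0. That count was 0 without either 48 h replicate, 14 and 7 without starved replicates 1 and 2, and 260 and 859 without 24 h replicates 1 and 2.

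A contrast of starved against N-supplied leaves in which dye effects cancel took 0.5 of the difference between the starvation ratio and the mean readdition ratio. It called 843 probes higher and 676 lower in starved leaves. The fit takes the arrays as independent, although starved RNA stands in all 3 comparisons. The error of a shared starved extract would add up in this contrast, and the standard errors and p-values below would be too small. Differences between replicates in starvation and at 48 h correlated at r = -0.24 on slide A and -0.22 on slide B. For starvation and 24 h, r was -0.15 and 0.004. For 24 h and 48 h, r was -0.02 and 0.005, where a starved extract shared by replicate number would give a positive r. Nitrite reductase was lower by -3.38 ± 0.11 (adjusted p = 6.01e-06), the rhodanese-like protein (LOC_Os09g36040) by -2.32 ± 0.11, CLC-a (LOC_Os12g25200) by -2.32 ± 0.12. Also lower were TIP1.1 (LOC_Os01g74450) at -2.24 ± 0.13, a glutaredoxin-like protein (LOC_Os12g35340) at -1.83 ± 0.18 and ferredoxin-2 (LOC_Os01g64120), at least 3.98-fold, a bound because its starved reading at 24 h lay at background. Higher were the tryptophan/tyrosine permease (LOC_Os03g14910) at 2.04 ± 0.12, beta-fructofuranosidase 1 (LOC_Os02g01590) at 2.02 ± 0.12, the papain family protease (LOC_Os03g54130) at 1.89 ± 0.10 and branched-chain amino acid aminotransferase 5 (LOC_Os03g12890), at least 2.96-fold. On the N list, 4 probes were higher and 2 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.248), with ammonium transporter 1 member 2 (LOC_Os04g43070) at 0.94 and 1 of the 2 nitrate reductase probes (LOC_Os08g36480/LOC_Os08g36500) at -0.75. With median centring alone 817 probes were higher and 397 lower. The count was 688 and 698 without starved replicates 1 and 2 and 803 and 827 without 48 h replicates 1 and 2. Of the named probes past the test, 62 of 78 passed with each replicate left out in turn.

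In this contrast 12 of 20 light harvesting probes were lower and none higher (13 lower and 1 higher adjusted over the list alone; list median -0.67, camera adjusted p = 2.04e-06, and adjusted p = 0.641 with an estimated correlation). Leaving out saturated readings ended the call (median -0.14, adjusted p = 0.447). Of 17 chlorophyll synthesis probes, 7 were lower on both counts (camera adjusted p = 0.0107, and adjusted p = 0.493 with an estimated correlation). Of 115 cytosolic ribosome probes 22 were lower and 4 higher (23 and 4 adjusted over the list alone; camera adjusted p = 0.000413, and adjusted p = 0.493 with an estimated correlation). Of 26 phenylpropanoid and flavonoid probes, 10 were higher and none lower (12 and 1 adjusted over the list alone; list median 0.41, camera adjusted p = 0.000814, and adjusted p = 0.493 with an estimated correlation). Markers of expanding cells were higher alongside, 5 of 14 probes (7 adjusted over the list alone; list median 0.56, camera adjusted p = 0.0147, and adjusted p = 0.915 with an estimated correlation), a call lost without starved replicate 2 (adjusted p = 0.0612) or 24 h replicate 1 (0.0924). It was also lost with print-tip loess (0.0503) and with no filter (median -0.0038, adjusted p = 0.98), and the phenylpropanoid call with no filter (0.0587). The pentose phosphate and reductant list was lower (5 lower, 1 higher; 5 and 2 adjusted over the list alone; camera adjusted p = 0.001, and adjusted p = 0.641 with an estimated correlation). That list's median of -0.09 went to -0.0015 with median centring alone, to -0.0020 without 24 h replicate 1 and to -0.01 and -0.05 without starved replicates 1 and 2, with the call kept each time. Photosystem subunits (7 lower, 1 higher on both counts) and amino acid synthesis (8 lower, 1 higher on both counts) were called at a camera adjusted p of 0.0465 each (adjusted p = 0.915 and adjusted p = 0.493 with an estimated correlation). The photosystem call was lost without starved replicate 1 (0.173) or 2 (0.0612), 24 h replicate 2 (0.176) or 48 h replicate 1 (0.0917). It was also lost with median centring alone (0.108), no background correction (0.094), marked spots kept (0.0717) and saturated readings left out (0.332). The amino acid call was lost with any 1 replicate left out except 48 h replicate 2, at adjusted p = 0.0801 and 0.0556 for the starved, 0.0752 and 0.0696 for the 24 h and 0.0656 for the other 48 h replicate. Its median went from -0.18 to -0.11 without 24 h replicate 2. It was also lost with median centring alone (0.0975), no background correction (0.0754), print-tip loess (0.0524) and saturated readings left out (0.0564). With the 24 h slide A numbers exchanged, the expanding cell call was lost without 24 h replicate 1 (adjusted p = 0.056). The photosystem (0.0921) and amino acid (0.137) calls were lost without 24 h replicate 2. Fry, which tests whether a list's probes move 1 way rather than against other probes, also called 1 of 6 lists for starvation, 4 of 8 at 24 h, 3 of 5 at 48 h, 0 of 3 for 48 h minus 24 h and 6 of 8 here.

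**Figure D3:**
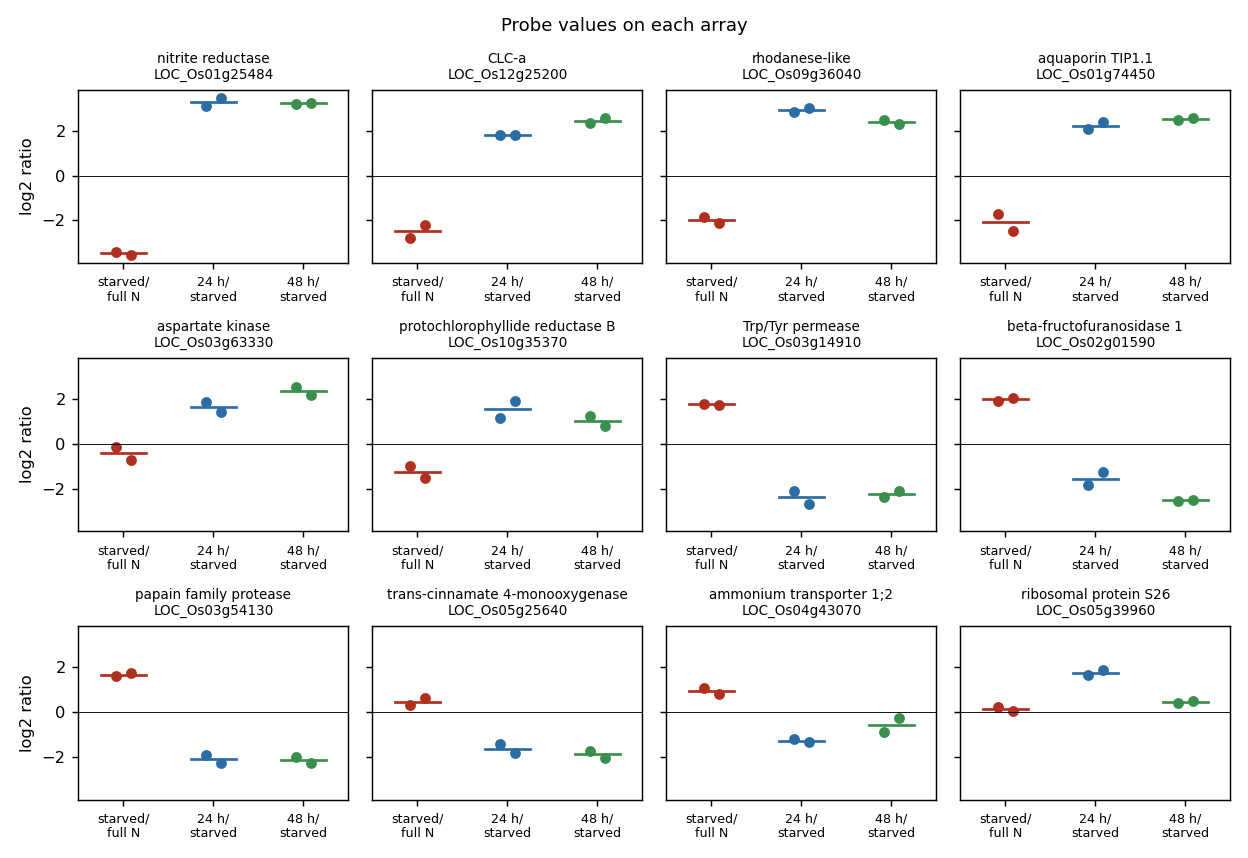
Log2 ratio of 12 named probes (y axis) in the 3 comparisons (x axis), with 1 point per array and a bar at the mean of the 2 arrays. Nitrite reductase stood at -3.48 for starved over full N leaves. Over starved leaves it stood at 3.31 at 24 h and 3.24 at 48 h, and ribosomal protein S26 at 1.76 at 24 h and 0.46 at 48 h.

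The deposited value table held 1 combined score per probe and comparison, with 2766, 2459 and 1977 values in comparisons 1, 2 and 3. Its scores are control over treated, opposite in sign to the ratios above, and their log base is not stated. With the sign turned, they correlated across matched probes with the ratios above at r = 0.80 for starvation, 0.84 at 24 h and 0.68 at 48 h. Of the called probes that matched, 160 of 162, 413 of 416 and 215 of 233 had the same sign. Between the deposited scores themselves, r was -0.46 for starvation against 24 h, -0.51 against 48 h and 0.56 between 24 h and 48 h.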

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

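Chosen after the result was seen were the tests of dye bias, of scan day and of shared or pooled starved extracts; the tests of saturation, signal level and single replicates were set before, and the condition for dye bias as the whole cause was changed after its value was seen.

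The difference between 48 h and 24 h of readdition passed its own test for 3 lists: the median log2 difference was -0.58 for cytosolic ribosome probes, -0.55 for plastid ribosome probes and 0.26 for markers of dividing cells. None of these calls held with an estimated correlation (adjusted p = 0.353, 0.973 and 0.973). Spots for hygromycin phosphotransferase, a bacterial gene outside the main measurement, lay above background in 0.608% of 5426 readings (exact 95% interval 0.419% to 0.853%). Empty spots did so in 0.142% of 7020 readings (0.0683% to 0.262%) and plant probes in 13.1%. The readings repeat the same spots over arrays and channels. The intervals take them as independent and do not measure the spread between spots or arrays.

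Cytosolic ribosome transcripts lay higher at 24 h than at 48 h. Signal level as the cause is argued against: of 10000 random lists matched on intensity, 100% had a median above the list's, and the lowest was -0.21. A single replicate is argued against too, since the highest difference over the 4 pairings of replicates was -0.47 (-0.52 with the 24 h slide A numbers exchanged). The arrays of the times shared 0 scan days, and median background was 479 to 897 at 48 h against 77 to 277 at 24 h, so scan day or labelling batch and time of readdition cannot be told apart. A passing rise in ribosome synthesis after N returns stays an untested hypothesis.

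Light harvesting probes were lower in starved leaves (list median -0.98), and their list median on readdition was 0.02 at 24 h and 0.23 at 48 h. Saturated members had a median of 0.48 at 48 h and reached up to 0.71 in the mean of the times. The control on readdition arrays was starved leaves, so a saturated control by itself overstates a rise. Dye bias as the whole cause stays open: the list median with the dye cancelled was -0.67, but 13 of 20 members were saturated. Of the 7 with no saturated pixel only 2 passed with the dye cancelled, at -0.70 and -0.65 (1 probe each of LOC_Os02g10390 and LOC_Os11g13890). Another probe of LOC_Os11g13890 with no saturated pixel stood at 0.07 (limma adjusted p = 0.682). Dye bias as a part stays open too, as the list median of the mean of the 3 comparisons was -0.24. Saturation hiding the rise also stays open, though only saturated treated readings could hide one. Over the 3 comparisons such readings stood on 0 arrays for LOC_Os04g38410, against 5 with a saturated control. For LOC_Os01g41710 they stood on 4 arrays, against 4 with a saturated control. The 7 members with no saturated pixel had a median readdition ratio of -0.13. Their starved median was -0.25, too small a fall to test a return. A slower return of these transcripts than of nitrite reductase may also account for it and was not tested.

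Most probes that passed in starvation had a ratio of the other sign on readdition, and the covariance over all probes was negative. Chance values of starved extracts shared by replicate number are argued against as the whole source of that covariance. The smaller ratio of observed to simulated covariance was 4.72. A single starved RNA pool on all arrays stays open, because arrays with different replicate numbers still had a mean r of -0.39, and the labels do not say how the starved extract was shared. Part of the excess may come from it.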

How the results depend on the processing

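The replicate block, saturated readings left out, exchanged slide numbers and some list settings were added after seeing the data. A random block for scan date was not run, since each comparison had its own day, and Aquantile scaling leaves log ratios unchanged by construction. Of plant spots not marked, 64.0% to 84.5% per array read below their local background in Cy5 and 44.6% to 85.9% in Cy3. This limits the number of probes tested. At 48 h the median foreground was 157 to 311, against a median background of 479 to 897. Of values for counts and correlations under alternatives 168 stayed within range and 68 moved. Of values for called lists 367 kept their direction and call and 83 lost the call. Of values for named probes 454 lost the call, 48 gained it and 4 that had passed reversed. The other 3215 count as unchanged, which includes values that changed sign without passing in either fit. They also include the values under Aquantile scaling, and the authors' table was judged by sign alone. Causes were not tested, though fewer arrays leave fewer degrees of freedom. Replicate ratios correlated across probes at r = 0.57 for starvation, 0.51 at 24 h and 0.77 at 48 h. The fit pools the spread of these comparisons, so a standard error is not a comparison's own precision. The ratios for starvation and 48 h do not depend on the 24 h arrays. Their counts without a 24 h replicate therefore moved through the pooled spread and its degrees of freedom alone. Whether unequal spread between replicates moved the other counts was not tested. Probes changed, in the order starved, 24 h and 48 h, were 40, 360 and 454 with no filter, 590, 262 and 1671 with array weights, 0, 46 and 1744 with only the arrays compared, 226, 487 and 370 at an absolute log2 ratio of at least 1, and 145, 589 and 388 with the replicate block. With the 24 h slide A replicate numbers exchanged, 606 changed at 24 h without replicate 2. The contrast that cancels the dye gave 247 at an absolute log2 ratio of at least 1, and the dye mean 224 with median centring. The correlation of starvation with readdition was -0.43 at 24 h and -0.35 at 48 h with no filter, and -0.46 at 24 h in the authors' table. That of 24 h with 48 h was 0.71 with print-tip loess, 0.66 with median centring, 0.55 with no filter and 0.56 in the authors' table. Lists called were 0 with an estimated correlation in each comparison and contrast, 3 for starvation with no background correction, 8 at 48 h with median centring, 1 at 48 h with no filter, and 5 for the contrast that cancels the dye with saturated readings left out. In the authors' table, with the sign turned, LOC_Os12g32760 reversed at 48 h (0.10), LOC_Os10g40720 at 24 h (0.0501) and 48 h (0.42) and LOC_Os12g19394 at 48 h (0.17). With no filter the expanding cell call was lost at 24 h (adjusted p = 0.199) and 48 h (adjusted p = 0.801), and the phenylpropanoid call at 48 h (adjusted p = 0.189). Leaving out 1 replicate leaves an arm with 1 array, assumed to vary like the others, and gave 7 to 620 probes for starvation, 417 to 1018 at 24 h, 0 to 1137 at 48 h, 0 to 1 for 48 h against 24 h, 688 to 1876 with the dye cancelled and 0 to 859 for the dye mean. Lists called were then 3 to 6, 5 to 8, 4 to 6, 2 to 7 and 6 to 9 for the same comparisons without the dye mean. Correlations ranged from -0.55 to -0.42 and from -0.50 to -0.40 for the reversal at 24 h and 48 h, and from 0.58 to 0.69 between 24 h and 48 h.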

Other observations

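The word scan was chosen after the data were seen, and the test of neighbouring genes was set before, but its deciding rule was changed after its value was seen.

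Lists that were not called held single movers in the contrast that cancels the dye, where higher means higher in starved leaves. Of 97 oxidative stress probes, 12 were higher and 18 lower (14 and 18 adjusted over the list alone, camera adjusted p = 0.528). Heat shock and chaperone probes gave 12 higher and 7 lower of 58 (14 and 7 adjusted over the list alone, camera adjusted p = 0.625), and autophagy and protease probes 9 and 5 of 41 (10 and 6 adjusted over the list alone, camera adjusted p = 0.528). Cytokinin and gibberellin probes gave 3 higher and 7 lower of 20 (camera adjusted p = 0.528), aquaporin and ion transport probes 3 and 6 of 19 (0.472), Calvin cycle probes 4 and 6 of 26 (0.528), photorespiration probes 3 and 0 of 10 (0.528) and chlorophyll breakdown and senescence probes 3 and 4 of 14 (0.779). Of the others, pathogenesis-related probes gave 4 and 6 of 20 (0.779), MYB factors 5 and 6 of 44 (0.783), WRKY factors 1 and 1 of 12 (0.783), starch and sucrose 3 and 3 of 20 (0.783), glycolysis and organic acids 2 and 3 of 38 (0.951), proteasome and ubiquitin 3 and 2 of 56 (0.783), amino acid and peptide transport 1 and 3 of 18 (0.783), phosphate starvation 1 and 0 of 8 (0.528), plastid ribosome 0 and 3 of 33 (0.0585), and hormone probes 4 and 1 of 17 (0.4). Among tissue markers, lignifying vascular, epidermal and root probes each had 1 lower and 0 higher, of 5, 6 and 8 (0.528, 0.583 and 0.912), and dividing cell probes 2 higher and 1 lower of 24 (0.912).

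A scan of 225 words from the gene descriptions gave further groups. Of 14 probes with the word permease, 3 of them on a fixed list, 5 were lower at 24 h (median -0.35, camera adjusted p = 0.00725, and adjusted p = 0.778 with an estimated correlation) and 4 at 48 h. Of 13 aquaporin probes, for water channels and all on a fixed list, 4 were lower in starved leaves (camera adjusted p = 0.00152, and adjusted p = 0.967 with an estimated correlation) and 3 were higher at 48 h. Of 11 probes with the word facilitator, 1 of them on a fixed list, 3 were higher in starved leaves (camera adjusted p = 0.0156, and adjusted p = 0.967 with an estimated correlation).

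That genes next to each other on the chromosome share their response to N was tested over 1093 pairs of neighbouring loci with different descriptions. Their r was 0.0428, and 6.6% of 1000 random pairings reached it. Over 92 neighbouring pairs with the same description r was 0.237, which 1% of random pairings of that size reached. The bound set before, an r within the random pairings (highest 0.0836), was met by the first value. That bound was too loose to argue against a shared response, since the 95% interval of r, -0.0165 to 0.102, reaches past it. The question stays open.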
